A study of Mus musculus with 15 samples.

How the data were processed

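Messenger RNA from the left ventricle was measured in 15 libraries, 5 per group, by stranded mRNA sequencing per the labels' protocols. The authors deposited 1 table of raw read counts, with a column per library and an Ensembl identifier and symbol per gene, and 0 columns without a matched sample. The submitters' processing notes name Trimmomatic, STAR, Cufflinks and edgeR and the genome builds GRCm38 and mm10, without roles or versions. The read counter, its strand setting and the annotation release are not given in the sources used here. The deposited counts are whole numbers with totals that differ between libraries, so no normalization had been applied to them. Of 47069 gene identifiers, 46488 are in the GENCODE M21 annotation of GRCm38, which supplied the positions of genes. 80 symbols occurred more than once in the table, and genes were therefore handled by identifier. How reads shared by overlapping, antisense or near-identical genes were counted is not given, so values of such genes, Erdr1 and its neighbours among them, are uncertain.

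Groups were taken from the sample titles. The replicate numbers in the titles are not shared between groups. They were read as animal numbers, and a number in the descriptions as the sequencing run, although the labels explain neither. If libraries of a group do not come from separate animals, p-values measure only the spread between these libraries. Replicate pairs were compared by a chi-square test of their counts over genes with at least 50 counts, and the lowest value per gene was 10.7 over 30 pairs, so no library was treated as a repeat of another. Totals of 32978702 to 103356830 counts per library set the counting error, and floors cover counting error only, while standard errors and intervals of fold changes also carry the spread between libraries. A floor of 3 counts over a group was used where all its libraries had 0.

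Each pair of groups was tested with edgeR 4.0.16 in R 4.3.3, on the 10 libraries of that pair, with TMM scaling, filterByExpr, glmQLFit and glmQLFTest, two-sided, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Errors of log2 fold changes are standard errors. Group levels are CPM (counts scaled to a common library total) with TMM factors from all 15 libraries, as mean ± SD. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and each list's members were also adjusted over the list alone. Of 51 lists written before the data were examined, 49 had at least 5 genes tested. Camera with an estimated correlation and fry were the other set tests, and fry tests whether a list moves one way without comparing it with other genes. A list shifted in simulated counts was tested with camera at the preset correlation only, so the power with an estimated correlation was not measured. Scores are means of log2 CPM over list members, compared by exact permutation tests over all arrangements. On simulated counts with 200 changed genes, false calls were 4.38% of calls for PBS against sham, 6.25% for rHCI against PBS and 2.78% for rHCI against sham. Genes were drawn independently in these counts, so the shares do not cover joint variation of genes between hearts.

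Genes to be named were set by a rule. It took per comparison the 8 largest rises and falls among genes that passed, had at least 5 CPM in the higher group, had groups without overlap and carried a symbol that is not a predicted or clone name. Where none passed, it took the 5 of each direction with the smallest unadjusted p. It added up to 4 members of each list described, those with the largest change among genes that passed or otherwise the 2 with the smallest p, and always Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1, Glo1, Ager and Hagh. The text names some of the list members the rule gives, and that choice was made after values were seen.

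The alternatives were RLE factors, DESeq2 1.42.0, limma-voom with quality weights, other filters on low counts, all 15 libraries in 1 fit, the sequencing run as a covariate, the shared run alone, a minimum fold change of 1.2 (glmTreat), a tissue composition covariate for the comparisons of PBS with sham and of rHCI with PBS, other genes in the infarct score, and each replicate left out in turn. Leaving out rHCI 1 and rHCI 13 together was added after the data were seen. Other splits of the libraries were drawn 100 times per comparison. The remaining 2 lists had fewer than 5 genes tested and were left out of the list tests. No library was left out of the main tests.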

Results

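Messenger RNA from the left ventricle of C57BL mice was sequenced in 15 libraries, 5 from each of 3 groups. In the PBS and rHCI groups a myocardial infarct was followed on day 7 by an injection into the heart muscle, of saline in the PBS group and of a hydrogel named rHCI in the other, and the tissue was taken 2 days later. The rHCI hydrogel is made from recombinant human collagen type I, the main structural protein of the scar. The sham group was matched for age and had no infarct. The labels give no day of injection for it, so infarct and injection cannot be told apart in comparisons with sham. They also give no time of day of collection, so a difference in it cannot be told apart either. The sham replicate numbers, 16 to 20, all follow those of the infarcted groups, 1 to 14. If these numbers follow the order of handling, that order is confounded with the infarct too. Phrases such as after the infarct, changed by the infarct or infarct score cover all of these. The deposited table held read counts for 47069 genes. Total counts in the sham group were 83523371 in Sham 16, 53211878 in Sham 17, 60050350 in Sham 18, 57122306 in Sham 19 and 100899246 in Sham 20. In the PBS group they were 32978702 in PBS 2, 103356830 in PBS 6, 52299767 in PBS 9, 77737269 in PBS 12 and 58686083 in PBS 14. In the rHCI group they were 48699092 in rHCI 1, 48723170 in rHCI 3, 56679793 in rHCI 7, 62577074 in rHCI 11 and 54848425 in rHCI 13. Mitochondrially encoded genes took 16.4% ± 0.769 of the counts in sham hearts (SD, n = 5), 11.2% ± 1.04 in PBS hearts and 12.2% ± 1.73 in rHCI hearts. A number in the labels, read here as a sequencing run, was shared by 12 libraries. PBS 6 carried another such number, and so did rHCI 1 and Sham 19. No pair of libraries within a group differed by less than sampling noise. The first principal component held 86.5% of the variance of the 2000 most variable genes, with all sham libraries on one side and all infarcted libraries on the other.

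The comparison of PBS with sham hearts asked what differed between an infarcted ventricle injected with saline and one without an infarct. Cthrc1, a protein secreted by fibroblasts of healing scars (ENSMUSG00000054196; GRCm38 chromosome 15, 39076932 to 39087121), rose from 0.129 ± 0.0518 to 93.8 ± 20.7 CPM (counts scaled to a common library total, SD, n = 5 per group), a log2 fold change of 9.44 ± 0.25 (SE). Spp1, which encodes osteopontin (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050), rose from 0.482 ± 0.137 to 119 ± 38.4 CPM. Nppa, the atrial natriuretic peptide gene (ENSMUSG00000041616; chromosome 4, 148000722 to 148002079), rose from 250 ± 50.7 to 3226 ± 593 CPM, and Col1a1, a chain of collagen type I (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042), from 176 ± 23.7 to 4653 ± 771 CPM. Myh6, the adult myosin heavy chain of mouse heart muscle (ENSMUSG00000040752; chromosome 14, 54941921 to 54966927), fell from 29638 ± 2469 to 14693 ± 2797 CPM.

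Of the 8 largest rises among genes at 5 CPM or more, the remaining members were Adamts16, C1qtnf3, Cemip, Saa3, Sprr1a and P4ha3. Adamts16, a secreted metalloprotease gene (ENSMUSG00000049538; chromosome 13, 70727802 to 70841811), had 0 counts over the 5 sham libraries and 5.44 ± 2.16 CPM in PBS hearts. Against a floor of 3 counts over the sham group it was at least 571-fold higher. The log2 fold changes were 10.08 ± 0.62 for C1qtnf3, 8.37 ± 0.40 for Sprr1a and 7.60 ± 0.28 for P4ha3, which encodes a subunit of the enzyme that hydroxylates collagen prolines. Cemip, a hyaluronan-degrading protein gene, had 8.91 ± 0.45 and reached 10.26 without Sham replicate 19. Saa3, an acute-phase protein gene, had 8.86 ± 0.27 and reached 9.75 without Sham replicate 20. The 8 largest falls were smaller. They were Fam222a (log2 fold change −3.16 ± 0.38), Fam107a (−2.42 ± 0.12), the orphan nuclear receptor gene Nr4a1 (−2.30 ± 0.33), Arrdc2 (−2.19 ± 0.10), the potassium channel subunit gene Kcnv2 (−2.15 ± 0.27), the kinase gene Sik1 (−2.05 ± 0.21), Cngb3 (−1.97 ± 0.27) and Lingo3 (−1.88 ± 0.17).

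**Figure D1:**
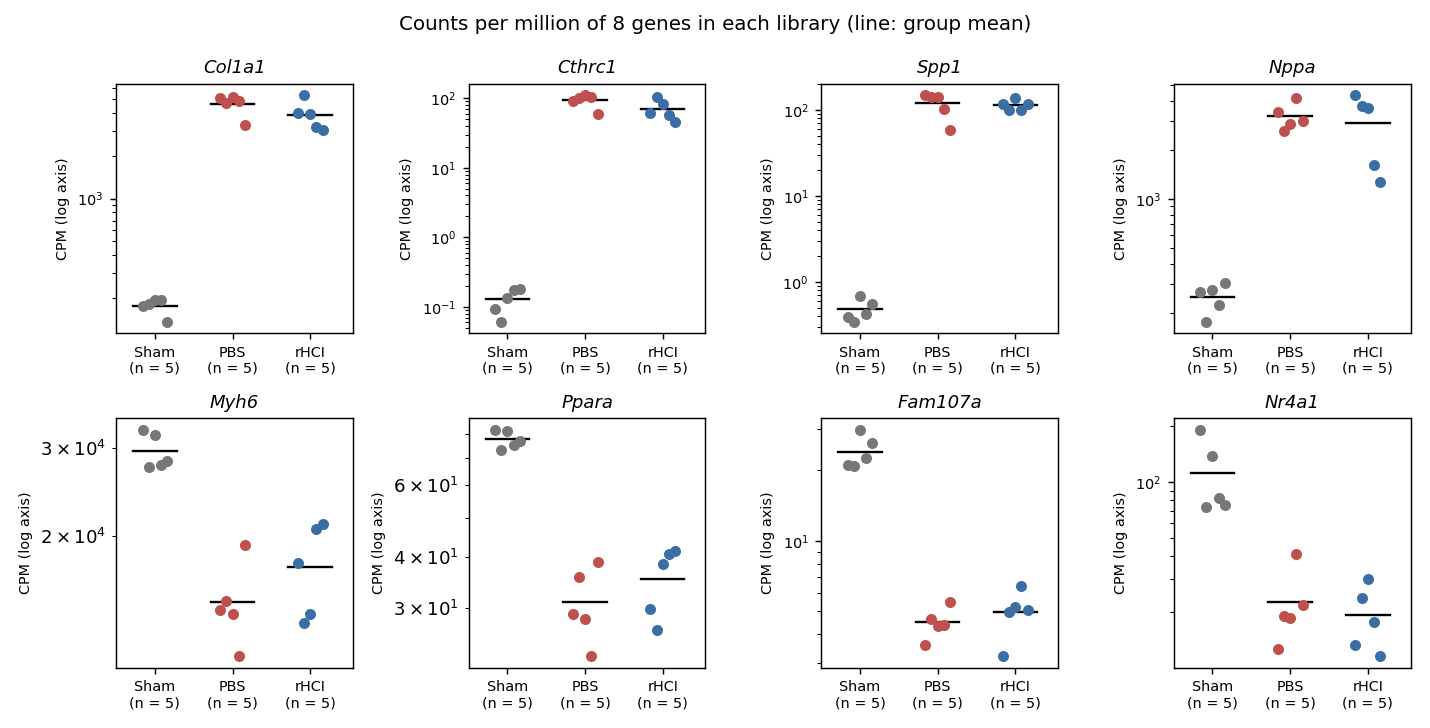
CPM on a log axis for 8 genes in each library of the sham, PBS and rHCI groups, with points in the order of the replicate numbers and a line at the group mean. Cthrc1 had a mean of 0.129 CPM in sham, 93.8 in PBS and 70.3 in rHCI hearts, while Myh6 had means of 29638, 14693 and 17326 CPM.

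Genes of the contractile and metabolic machinery of heart muscle fell as groups. Of 22 sarcomere genes measured, 18 fell and 0 rose (19 lower adjusted over the list alone), with a median log2 fold change of −0.56. Scaled by the library total in place of TMM, that median was −0.29. Ttn, the giant spring protein of the sarcomere, fell from 3430 ± 799 to 1510 ± 643 CPM (SD, n = 5), and Tnni3, cardiac troponin I, from 4121 ± 253 to 2181 ± 318 CPM. Of 26 genes of calcium handling and ion channels, 22 fell and 0 rose, the same count adjusted over the list alone, and the sodium channel subunit gene Scn4b had a log2 fold change of −1.33 ± 0.23. In fatty acid oxidation 27 of 28 genes fell (27 adjusted over the list alone). Ppara, its transcriptional regulator (log2 fold change −1.33 ± 0.11), and the thiolase gene Acaa2 (−1.05 ± 0.13) were among them. All 23 genes of the TCA cycle list, all 41 nuclear-encoded genes of oxidative phosphorylation and all 13 mitochondrially encoded genes fell, with the same counts adjusted over each list alone. Among them Cox7a1 fell from 507 ± 33.9 to 253 ± 42.2 CPM and mt-Co3 had a log2 fold change of −0.91 ± 0.08. With an estimated correlation between genes, adjusted p = 0.319 for fatty acid oxidation and adjusted p = 0.313 for the others of these lists in limma's camera test, so no list call held there. That setting called 0 of 49 lists in every comparison, even where all members of a list changed one way. The lack of a call there, here and below, therefore does not argue against a shift. The mitochondrial share of counts, 16.4% in sham and 11.2% in PBS hearts, moved with these lists. Glycolysis genes went both ways, with 7 higher and 14 lower of 23 (7 and 15 adjusted over the list alone; camera adjusted p = 0.158). The lactate exporter gene Slc16a3 rose (3.43 ± 0.13) and the heart lactate dehydrogenase gene Ldhb fell (−0.89 ± 0.08).

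Wall stress and fetal program genes, which ventricular muscle re-expresses under load, were higher for 13 of 15 and lower for 2 (the same counts adjusted over the list alone; adjusted p = 0.415 with an estimated correlation). Myh7, the fetal myosin heavy chain (ENSMUSG00000053093; chromosome 14, 54970684 to 54994626), rose from 466 ± 222 to 1420 ± 114 CPM. Nppb, the brain natriuretic peptide gene, rose from 229 ± 86.5 to 505 ± 214 CPM, with PBS 12 at 875 CPM and the others between 350 and 495. The stress cytokine gene Gdf15 had a log2 fold change of 2.93 ± 0.42. In the list of methylglyoxal detoxification and RAGE, which concerns a reactive by-product of sugar breakdown, 6 of 13 genes rose and 6 fell (6 and 6 adjusted over the list alone). Glo1, the glyoxalase that removes methylglyoxal (ENSMUSG00000024026; chromosome 17, 30584936 to 30626871), fell from 84.8 ± 3.43 to 66.0 ± 4.34 CPM, and Hagh, the next enzyme of that pathway, from 55.3 ± 3.44 to 48.3 ± 2.63 CPM. Hagh did not pass against a minimum change of 1.2-fold (adjusted p = 0.895 by edgeR). Ager, the receptor gene RAGE, rose by 2.59 ± 0.70 on the log2 scale at low levels, with PBS 6 at 3.37 CPM and the other PBS libraries between 0.338 and 0.633. Without PBS replicate 6 its log2 fold change was 1.31. The score of the lung and liver list, which had too few genes to be tested, was −0.140 in PBS 6 and −1.90 to −1.51 in the other PBS libraries. The cause was not tested. Lgals3, galectin 3, rose from 1.72 ± 0.179 to 52.9 ± 13.6 CPM. In the oxidative stress list 11 genes rose and 13 fell of 27 (the same adjusted over the list alone), with higher Hmox1 (2.21 ± 0.12) and higher Slc7a11, a cystine transporter gene (4.99 ± 0.50).

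Most genes of the matrix lists were higher. All 37 collagens and matrix proteins were higher (37 adjusted over the list alone), with a median log2 fold change of 2.93. Col3a1 rose from 375 ± 56.5 to 7134 ± 1038 CPM, elastin (Eln) from 80.2 ± 17.7 to 3112 ± 622 CPM and fibronectin (Fn1) from 68.1 ± 9.34 to 1840 ± 264 CPM. Of 21 genes of collagen processing and crosslinking 20 rose, and the crosslinking enzyme gene Lox went from 7.23 ± 0.966 to 384 ± 94.6 CPM. Of 20 activated fibroblast genes 19 rose, with a median of 3.85, and Sfrp2 reached 345 ± 68.1 CPM from 5.02 ± 1.06. Resting fibroblast genes were higher for 12 and lower for 3 of 16. Among matrix proteases and their inhibitors 24 rose and 3 fell of 28, including the macrophage elastase gene Mmp12 (7.38 ± 0.29) and the inhibitor gene Timp1 (4.88 ± 0.16). Collagen receptors rose for 16 of 18, among them the inhibitory immune receptor gene Lair1 (2.88 ± 0.21) and the integrin gene Itga11 (2.87 ± 0.17). TGF-beta signalling, a driver of scar formation, had 19 higher and 2 lower of 24, with Tgfb3 at 152 ± 19.5 against 20.4 ± 0.900 CPM. Adjusted over each list alone these counts were the same, except 1 lower collagen receptor. For each of these lists adjusted p = 0.313 with an estimated correlation.

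Most immune lists were higher. All 20 macrophage genes rose, with a median of 2.17, and Ms4a7 went from 1.74 ± 0.276 to 27.8 ± 5.63 CPM. The lipid-associated and scar macrophage list had 13 higher and 1 lower of 14, with Gpnmb at 77.7 ± 27.6 against 1.14 ± 0.550 CPM and Arg1, arginase 1, at 9.74 ± 1.66 against 0.0571 ± 0.0389 CPM. Monocyte genes were higher for 12 of 13, neutrophil genes for 9 of 11, T and NK cell genes for 19 of 22 and dendritic cell genes for 10 of 11. Lists not called by camera were those of resident-like macrophages, with 8 higher and 3 lower of 14 (camera adjusted p = 0.345), mast cells, with 3 higher of 6 (camera adjusted p = 0.194), and B and plasma cells, with 11 higher and 1 lower of 14 (camera adjusted p = 0.0524). The B and plasma cell list was called without Sham replicate 16 (0.0230), 17 (0.0106), 19 (0.0487) or 20 (0.0489), and without PBS replicate 6 (0.0476) or 9 (0.0186). Camera also called it with RLE factors (adjusted p = 0.0487) and with all 15 libraries in 1 fit (adjusted p = 0.0245). The neutrophil gene S100a8 had 2.89 ± 1.75 CPM in PBS hearts and 0.278 ± 0.116 in sham hearts. Cytokines and chemokines had 26 higher and 2 lower of 31, including the interleukin 1 antagonist gene Il1rn (5.61 ± 0.55) and the chemokine gene Cxcl5 (5.08 ± 0.42). All 25 interferon response genes rose, with a median of 1.10, among them Zbp1 (2.68 ± 0.15) and Mx1 (2.49 ± 0.24). Antigen presentation rose for 17 of 18, with the class II regulator gene Ciita at 2.43 ± 0.17, and complement for 16 of 17, with the receptor gene C3ar1 at 3.37 ± 0.13. Adjusted over each list alone these counts were the same, except 1 lower dendritic cell gene. With an estimated correlation adjusted p = 0.386 for the neutrophil list and adjusted p = 0.313 for the others that camera called.

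Endothelial genes did not move together. Of 21 measured, 8 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.871), with a higher Erg, an endothelial transcription factor gene (0.87 ± 0.08), and a lower Rgcc (−1.67 ± 0.09). Angiogenic factors and receptors had 16 higher and 8 lower of 27 (the same adjusted over the list alone; adjusted p = 0.313 with an estimated correlation), and the hepatocyte growth factor gene Hgf had 2.74 ± 0.18. Camera called this list at adjusted p = 0.0470, and did not without Sham replicate 17 (0.0538), PBS replicate 12 (0.0607) or PBS replicate 14 (0.0552). Cell cycle genes were higher for 26 of 27 and lower for 1 (26 and 1 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). The mitotic genes Ccnb1 (3.86 ± 0.30) and Cdk1 (3.31 ± 0.24) were among them. Erythroid genes had 0 calls of 7 by edgeR, and 0 adjusted over the list alone.

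By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5921 genes were higher and 5653 lower in PBS than in sham hearts of 16207 tested, 71.4% in all. Of these 2679 were higher and 404 lower by more than 2-fold. The libraries of the groups did not overlap for 9600 genes, 59.2% of those tested, against 0.794% by chance. Every gene named above with a rise or fall passed at adjusted p under 0.05, and those among the 8 largest in each direction had adjusted p from 1.05e-10 to 3.08e-05. Of 49 lists tested, camera with a preset correlation of 0.01 called 24 higher and 7 lower, 0 held with an estimated correlation, and fry called 39. With a covariate made of the sarcomere score minus the matrix score, which separated the groups by itself, 3 genes were called.

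The comparison of rHCI with PBS hearts asked what the hydrogel changed 2 days after injection. No gene passed. The genes nearest to the threshold at 5 CPM or more were interferon-induced genes and Erdr1 in the lower direction, and Tnik, Plet1os, Ston2, Reps1 and Gfod1 in the higher. Ifit1, an antiviral gene (ENSMUSG00000034459; chromosome 19, 34640871 to 34650009), had 15.4 ± 1.04 CPM with rHCI and 19.9 ± 2.13 with PBS (SD, n = 5), Ifit3 20.7 ± 2.34 and 27.3 ± 3.13, Ifit2 33.5 ± 3.08 and 40.4 ± 2.47, and Isg15 8.73 ± 0.394 and 11.2 ± 1.31. Erdr1 (ENSMUSG00000096768; chromosome Y, 90784738 to 90816464) had 1.98 ± 1.25 CPM with rHCI and 5.97 ± 0.727 with PBS, with rHCI 13 at 4.21 CPM and the other rHCI libraries up to 1.60. Sham 18, without infarct or hydrogel, had 1.45 CPM, and the other sham libraries 4.64 to 6.80. The kinase gene Tnik had 29.2 ± 0.897 CPM with rHCI and 24.5 ± 1.79 with PBS. Log2 fold changes were 0.37 ± 0.10 for Plet1os, 0.42 ± 0.11 for Ston2, 0.14 ± 0.04 for Reps1 and 0.24 ± 0.07 for Gfod1.

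Of the 8 genes with the largest rises after the infarct, Adamts16 had a log2 fold change of −0.76 ± 0.27 (SE) between rHCI and PBS and C1qtnf3 one of −0.66 ± 0.38. Cemip had −0.57 ± 0.32, P4ha3 −0.50 ± 0.23 and Cthrc1 −0.41 ± 0.22. Saa3 had −0.08 ± 0.16, Sprr1a −0.09 ± 0.36 and Spp1 −0.06 ± 0.22. These 8 genes were chosen for high levels in the same PBS libraries, which by itself favours negative values here. Col1a1 had 3913 ± 922 CPM with rHCI and 4653 ± 771 with PBS, a log2 fold change of −0.25 ± 0.17. The log2 fold changes were −0.21 ± 0.15 for Col3a1, 0.24 ± 0.17 for Myh6, 0.01 ± 0.15 for Myh7, −0.14 ± 0.31 for Nppa, −0.06 ± 0.43 for Nppb, 0.04 ± 0.07 for Glo1 and −0.03 ± 0.04 for Hagh. Ager had −1.51 ± 0.65, and −0.23 without PBS replicate 6. None passed, with adjusted p from 0.871 to 0.987 by edgeR.

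Interferon, matrix, activated fibroblast, macrophage, collagen receptor and cell cycle lists, higher after the infarct, leaned lower with rHCI, and the sarcomere and oxidative metabolism lists, lower after the infarct, leaned higher, without a single member passing over all genes. Both directions use the same PBS libraries, which favours opposite signs. Genes also varied together between hearts, as in the infarct score described below, whose difference was −0.30 (exact permutation p = 0.286). The member counts that follow are therefore not counts of independent changes. All 25 interferon response genes were lower with rHCI, with a median log2 fold change of −0.19, and 15 passed adjusted over the list alone. In camera this list had adjusted p = 1.31e-19, but adjusted p = 0.610 with an estimated correlation and 0.318 by fry. Of 37 collagens and matrix proteins 36 were lower (median −0.23, with Lum at −0.23 ± 0.11), of 20 activated fibroblast genes 19 (median −0.29, with Wisp1 at −0.56 ± 0.19 and Sfrp2 at −0.55 ± 0.19), and of 20 macrophage genes 18 (median −0.17, with Cd68 at −0.30 ± 0.14 and Fcgr1 at −0.27 ± 0.11). The collagen receptors were lower for 18 of 18, including Lair1 at −0.39 ± 0.11. In the other direction, 28 of 28 fatty acid oxidation genes (median 0.17, with Acadl at 0.15 ± 0.09), 41 of 41 nuclear-encoded oxidative phosphorylation genes (median 0.12), 13 of 13 mitochondrially encoded genes (median 0.20, with mt-Co3 at 0.26 ± 0.12) and 21 of 22 sarcomere genes (median 0.12) were higher. None of these members passed adjusted over its list alone, and adjusted p = 0.610 with an estimated correlation for each of these lists. Cell cycle genes were lower for 26 of 27 (median −0.16, with Mcm2 at −0.29 ± 0.10; 0 adjusted over the list alone; adjusted p = 0.610 with an estimated correlation). The camera calls of the collagen receptors (adjusted p = 0.0683 and 0.409) and of the cell cycle list (0.0607 and 0.251) were lost without PBS replicate 12 and without rHCI replicate 13. Without rHCI 1 and rHCI 13 together, an exclusion chosen after the data were seen, the camera calls of fatty acid oxidation (adjusted p = 0.128), nuclear-encoded oxidative phosphorylation (0.0508) and the mitochondrially encoded genes (0.343) were lost as well.

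Camera had called the neutrophil, cytokine and atrial lists higher after the infarct at the preset correlation, but not with an estimated correlation. With rHCI these lists leaned the same way and were not called. Of 12 neutrophil genes 10 were higher with rHCI (median 0.16, camera adjusted p = 0.0756), of 32 cytokines and chemokines 21 (median 0.08, camera adjusted p = 0.0756) and of 9 atrial genes 7 (median 0.40, camera adjusted p = 0.2805), with 0 members passing adjusted over each list alone. With an estimated correlation adjusted p = 0.610, 0.610 and 0.729. The atrial score was 5.39 in rHCI 1 and 4.08 to 4.95 in the other rHCI libraries. Camera called the neutrophil list without PBS replicate 2 (4.42e-04) or 6 (0.0432) and without rHCI replicate 1 (0.0367) or 11 (5.44e-05), and within the shared run (0.0263). It called the cytokine list without PBS replicate 2 (0.00142) or 12 (0.0402) and without rHCI replicate 11 (1.26e-04), and the atrial list without rHCI replicate 13 (0.0141). In the dendritic cell list Ccl22, a chemokine gene, had 1.18 ± 0.264 CPM with rHCI and 0.637 ± 0.0990 with PBS and was the 1 member that passed adjusted over the list alone; the list itself had camera adjusted p = 0.915 and adjusted p = 0.961 with an estimated correlation.

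By edgeR's quasi-likelihood test 0 of 16383 genes passed, with a smallest adjusted p of 0.295, and 579 had an unadjusted p under 0.05 where chance gives 819. That count was 2066 without rHCI replicate 3 and 1435 without PBS replicate 14, and 362 without PBS replicate 2 and 375 without rHCI replicate 11, with 0 genes called by edgeR each time. It was 2019 with limma-voom. DESeq2 called 6 genes (Tnik, Ccl22, Gria1, Igkv8-30, Erdr1 and G530011O06Rik), and limma-voom with quality weights called 3 (Erdr1, G530011O06Rik and Gm15726). The edgeR test without rHCI replicate 13 called the same 3 as limma-voom. Gria1, Igkv8-30, G530011O06Rik and Gm15726 are named after their values were seen. Groups did not overlap for 85 genes, 0.519% against 0.794% by chance. Counts were simulated with the spread of these libraries, but with genes drawn independently. There the test recovered 10% of genes changed 1.2-fold, 66% at 1.5-fold and 96% at 2-fold. Among 10955 genes at 5 CPM or more, the 95% interval of the difference lay within 2-fold for 99.5% and within 1.5-fold for 95.9%. Camera called 7 lists higher and 14 lower of 49, and 0 were called with an estimated correlation or by fry.

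**Figure D2:**
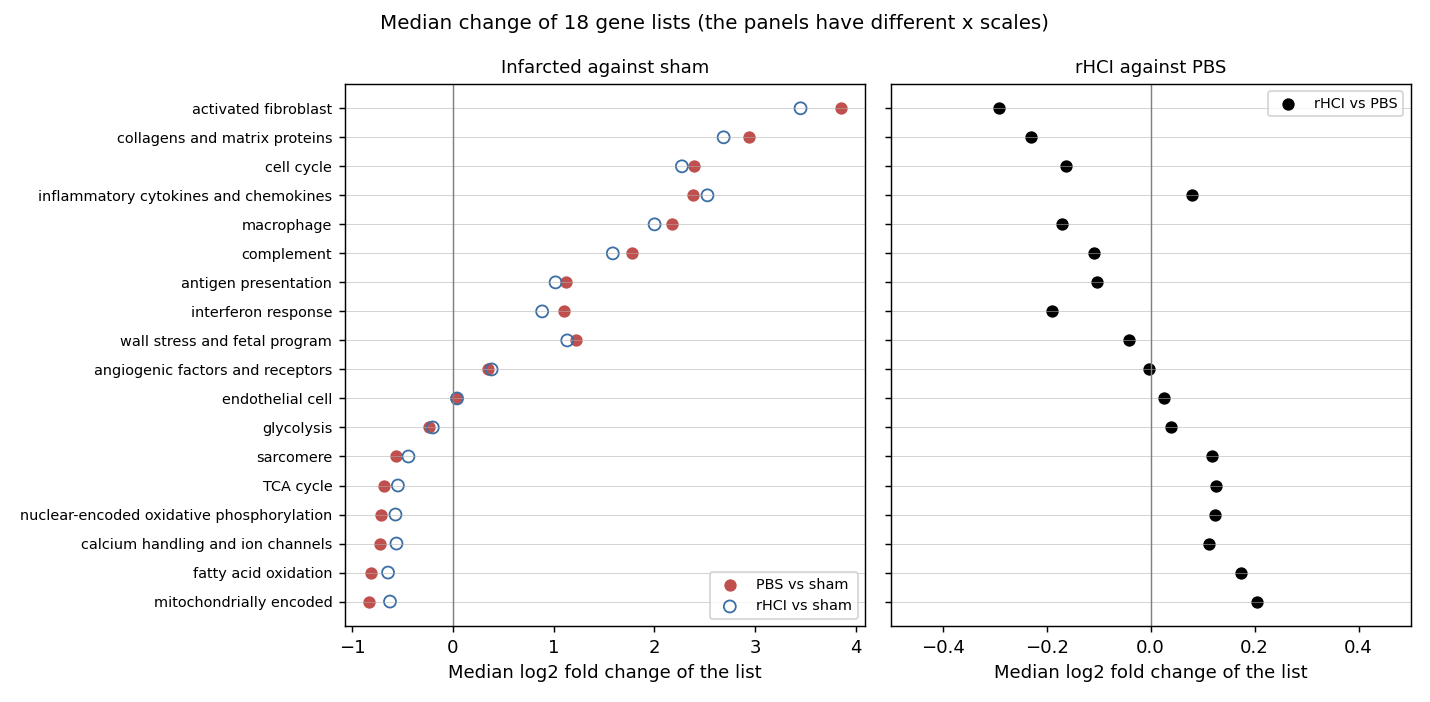
Median log2 fold change of each of a set of gene lists, on the left for PBS against sham (filled) and rHCI against sham (open), on the right for rHCI against PBS on a narrower scale. The activated fibroblast list had medians of 3.85, 3.45 and −0.29 in the 3 comparisons, and the fatty acid oxidation list −0.81, −0.64 and 0.17.

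The comparison of rHCI with sham hearts gave the distance of the hydrogel-treated ventricle from tissue without an infarct. Cthrc1 had 70.3 ± 22.9 CPM (SD, n = 5; log2 fold change 9.04 ± 0.32), C1qtnf3 29.4 ± 10.6 CPM (9.41 ± 0.43), Spp1 114 ± 15.2 CPM (7.88 ± 0.16) and Arg1 15.5 ± 7.25 CPM (7.98 ± 0.50). Saa3 (8.78 ± 0.34, and 9.66 without Sham replicate 20), Cemip (8.33 ± 0.57, and 9.67 without Sham replicate 19), Sprr1a (8.28 ± 0.56) and Mmp12 (7.21 ± 0.26) completed the 8 largest rises. The 8 largest falls were Fam222a (−2.83 ± 0.38), Nr4a1 (−2.52 ± 0.33), Fam107a (−2.26 ± 0.16), Sik1 (−2.20 ± 0.18), Arrdc2 (−2.19 ± 0.14), Rasd1 (−1.68 ± 0.24), Lingo3 (−1.63 ± 0.18) and Klf15, a metabolic transcription factor gene (−1.61 ± 0.22). Nppa (3.56 ± 0.34), Myh7 (1.63 ± 0.30), Col1a1 (4.49 ± 0.18), Col3a1 (4.05 ± 0.16) and Ager (1.08 ± 0.30) rose, and Myh6 (−0.76 ± 0.15), Glo1 (−0.31 ± 0.06) and Hagh (−0.22 ± 0.05) fell. Ager did not pass with all 15 libraries in 1 fit (adjusted p = 0.181 by edgeR). Nppb rose by 1.08 ± 0.43 at adjusted p = 0.0414 by edgeR, and did not pass without rHCI replicate 1, 3 or 7, or without Sham replicate 16, 17 or 20. It also did not pass within the shared run (adjusted p = 0.0652) or against a minimum change of 1.2-fold (adjusted p = 0.0793), and against that minimum Glo1 (adjusted p = 0.174) and Hagh (adjusted p = 0.815) did not pass either.

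All 37 collagens and matrix proteins (median 2.69), 20 of 20 macrophage genes (median 2.00), 18 of 20 activated fibroblast genes (median 3.45) and 25 of 25 interferon response genes (median 0.89) rose. In the other direction 19 of 22 sarcomere genes, 26 of 28 fatty acid oxidation genes, 41 of 41 nuclear-encoded oxidative phosphorylation genes and 13 of 13 mitochondrially encoded genes fell. These counts were the same adjusted over each list alone. With an estimated correlation, adjusted p was at most 0.420, the value for the mitochondrially encoded genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5487 genes were higher and 4781 lower of 16076 tested, 63.9% in all, with 2322 and 222 by more than 2-fold; against a minimum change of 1.2-fold 6157 passed. Camera called 25 lists higher and 7 lower of 49, 0 held with an estimated correlation, and fry called 39.

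Both infarcted groups were compared with the same 5 sham libraries. Of 15973 genes tested in both, 5319 were higher and 4669 lower in both, and 0 were called in opposite directions. Lists drawn independently would share 1978 and 1690 genes, and simulated unchanged groups against shared sham libraries shared 0. With the sham libraries split between the comparisons, 4637 higher and 3781 lower calls were shared on average, against 1666 and 1254 for independent lists. Across 16634 genes the fold changes had a covariance of 0.861, against 0.0152 simulated for shared sham libraries alone, and 0.845 with the sham libraries split. Genes are not independent replicates.

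An infarct score per library summarised 2753 genes higher and 291 lower in the 10 infarcted libraries than in sham, with the sham mean at 0. It was 3.35 ± 0.369 in PBS and 3.04 ± 0.481 in rHCI hearts (SD, n = 5 per group), with a sham SD of 0.138. The difference of −0.30 had p = 0.286 in a two-sided exact permutation test, of which the smallest possible value is 0.00794. Within the shared run the difference was −0.38 (exact permutation p = 0.257). It was −0.15 without rHCI replicate 13, −0.20 without rHCI replicate 11 and −0.20 without PBS replicate 12 (exact permutation p = 0.571, 0.508 and 0.468), and −0.18 with genes of any fold change in the score (exact permutation p = 0.214). Of 6 tissue lists scored in the same way none differed between rHCI and PBS, with exact permutation p from 0.151 to 0.651 and adjusted p from 0.429 to 0.651. The sarcomere list had 10.9 ± 0.157 with rHCI and 10.7 ± 0.139 with PBS, the matrix list 8.49 ± 0.379 and 8.77 ± 0.181, and the macrophage list 5.05 ± 0.156 and 5.22 ± 0.190 (mean log2 CPM, SD, n = 5). Over the genes changed by the infarct, the median difference between rHCI and PBS, signed so that a move toward sham is negative, was −0.08 on the log2 scale, averaged over 20 splits of the PBS libraries between the comparisons (range −0.15 to −0.00146). Data simulated without a hydrogel effect gave −4.64e-04. Genes were drawn independently there, so simulated hearts did not vary together in infarct score as the real ones did (2.49 in rHCI 13 to 3.80 in PBS 12). The simulated values, that of the covariance below included, therefore do not show what chance between hearts would give. The covariance of infarct and hydrogel changes was −0.0948, against −0.0146 simulated for shared PBS libraries alone. Of 100 arrangements of the PBS and rHCI labels, 10 gave a covariance as low, the real one included. Such arrangements keep the joint variation of genes, and were made for the covariance only. Over genes changed more than 2-fold the median was −0.17, and within the shared run, over all genes changed, it was −0.10. Without rHCI replicate 3 it was −0.13 and without rHCI replicate 13 it was −0.05.

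**Figure D3:**
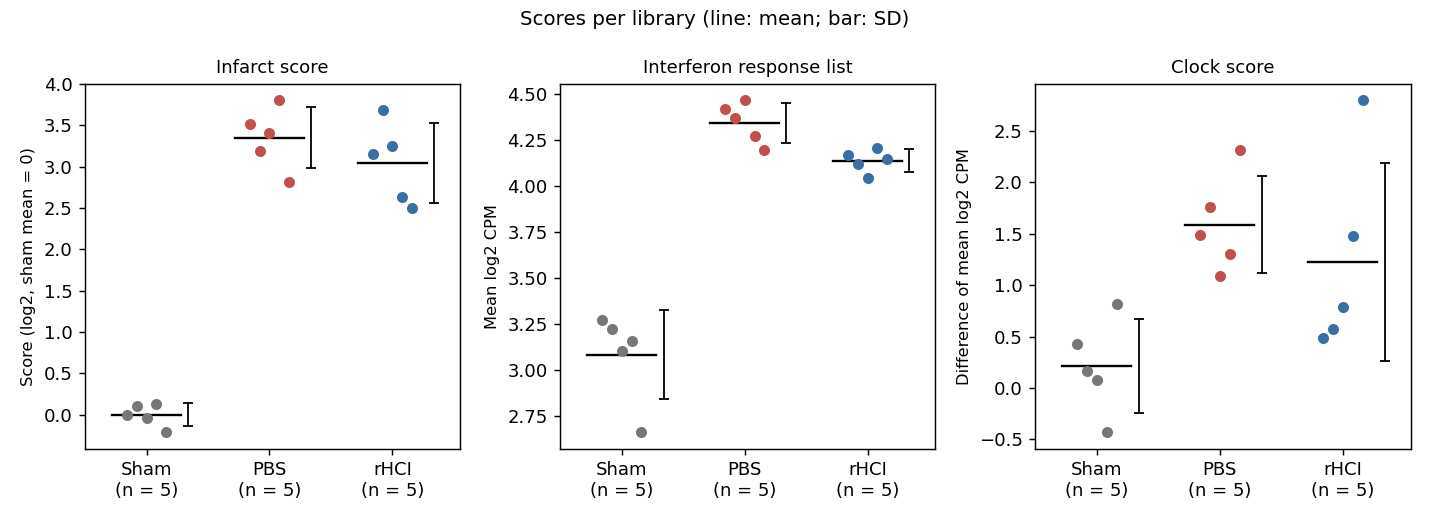
Infarct score, mean log2 CPM of the interferon response list and clock score (the difference between the arms of the circadian clock, described among the additional observations) in each library of the sham, PBS and rHCI groups (n = 5 each), with lines at the means and bars for the SD. The infarct score was 3.35 ± 0.369 in PBS and 3.04 ± 0.481 in rHCI hearts, with sham hearts around 0.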

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

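The tests of the clock and interferon patterns, the values set beside the cardiomyocyte tests as additions, and the exclusion of rHCI 1 and rHCI 13 together were chosen only after the result was seen. In groups of 5 libraries, a library whose gap to the nearest other exceeded 0.710 of the group's range was singled out. Of 335 groups examined 41 had such a library, where chance gives about 1 in 20, or 16.8. PBS 14 was singled out 9 times, Sham 18 and Sham 20 5 times each, PBS 6 4 times, and PBS 9, rHCI 7 and rHCI 11 0 times.

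PBS 14 had 3318 CPM of Col1a1 (others 4747 to 5207), 12.03 of P4ha3 (22.3 to 25.8), 118 of Tgfb3 (154 to 168), 20.5 of Mmp12 (39.3 to 43.7), 19.6 of Hmox1 (27.8 to 29.2), 30.8 of C3ar1 (43.1 to 46.0) and 23.4 of Cd68 (35.7 to 40.04). Its matrix score was 8.46 (8.81 to 8.93) and its Ttn level 2646 CPM (1119 to 1394). PBS 6 stood high for C1qtnf3 at 99.5 CPM (27.0 to 44.8), Ager at 3.37 (0.338 to 0.633) and the skeletal muscle genes Tnnt3 at 7.36 (1.15 to 1.31) and Myh8 at 14.3 (0.04998 to 0.268). PBS 12 stood high for Nppb at 875 CPM (350 to 495) and Erdr1 at 7.26 (5.53 to 5.81), and PBS 2 for S100a8 at 5.91 (1.61 to 2.82).

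In the rHCI group rHCI 1 had the atrial genes Myl7 at 145 CPM (others 25.1 to 49.98) and Sln at 43.4 (4.94 to 10.8), and Lair1 at 6.42 (7.82 to 8.30). rHCI 13 had Dbp at 162 CPM (36.2 to 66.5), Erdr1 at 4.21 (1.305 to 1.60) and Gm15726 at 0.424 (0 to 0.0737). rHCI 3 had Tnnt3 at 1.77 CPM (0.880 to 1.13) and Mcm2 at 15.4 (11.3 to 12.2). Among sham libraries, Sham 20 was low for Ctss at 12.04 CPM (15.2 to 16.2), C3ar1 at 3.20 (4.12 to 4.41), the macrophage score at 2.63 (2.98 to 3.09), the interferon score at 2.66 (3.10 to 3.27) and the first principal component at −80.1 (−71.0 to −67.7). Sham 18 was high for Gdf15 at 5.48 CPM (1.69 to 2.32), Lox at 8.91 (6.65 to 7.20), Sfrp2 at 6.85 (4.15 to 4.83), Gpnmb at 2.09 (0.694 to 1.06) and Hgf at 0.990 (0.572 to 0.687). Sham 19 had Cemip at 0.137 CPM (0 to 0.0226), Msln at 6.20 (2.84 to 3.60) and Per3 at 6.00 (10.3 to 11.9). Sham 16 had Slc16a3 at 2.10 CPM (1.33 to 1.53) and Tnnt3 at 0.663 (0.327 to 0.412), and Sham 17 had Ciita at 1.53 (0.761 to 0.981) and Lum at 86.0 (69.4 to 73.1).

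Sarcomere, calcium handling and metabolic genes were lower in PBS than in sham hearts. The fatty acid oxidation score fell by more than the sarcomere score, with a difference of −0.216 (exact permutation p = 0.0159, n = 5 per group), inside the bound of 0.3 set for it before the data were examined. A difference inside that bound had been predicted for a smaller share of heart muscle RNA as the whole cause. If both lists were expressed in heart muscle alone, however, a smaller share would lower them equally. The difference was larger than the SD in PBS (0.131) and in sham hearts (0.0810). For these 2 lists it therefore argues, weakly, against a smaller share as the whole cause. A loss of heart muscle RNA alone would raise the markers of all other cell types alike. The macrophage minus endothelial score rose by 2.34 (exact permutation p = 0.00794), which argues against such a loss alone. A gain of macrophages would itself lower the share of heart muscle RNA, so this score cannot decide on a smaller share. Scaled by the library total in place of TMM, the sarcomere median was −0.292 (−0.563 with TMM) and 19 of 22 members were lower. That misses the bound of −0.3 set beforehand by little, but the score by library total still differed by −0.321 (exact permutation p = 0.00794), so the scaling may account for part of the fall and not for all of it. A smaller share as part of the cause and lower expression within heart muscle cells both stay open, and these values do not tell them apart.

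Interferon response genes were lower with rHCI than with PBS, with scores of 4.14 ± 0.0623 and 4.34 ± 0.110 (difference −0.207, exact permutation p = 0.0159, n = 5 per group). In the shared run the difference was −0.209 (exact permutation p = 0.0571, n = 4 per group), which argues against the sequencing run as the cause. The interferon score minus the macrophage score differed by −0.0338 (exact permutation p = 0.746), which leaves fewer macrophages in the rHCI hearts open without showing them. The macrophage score itself differed by −0.173 (exact permutation p = 0.151). Single libraries went both ways. rHCI 3 had a macrophage score of 5.25 and an interferon score of 4.12, against 5.18 and 4.37 in PBS 6. PBS 14 was low in both within its group (4.91 and 4.20). The exact permutation p adjusted over the lists scored was 0.667, but a single shifted list could not go below 0.389 in this design, so chance and an effect of the hydrogel cannot be told apart.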

How the results depend on the processing

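Leaving out rHCI 1 and rHCI 13 together and the comparison of list scores with sham were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. For named genes, 1461 values of PBS against sham and 488 of rHCI against sham kept their side of the threshold. Those that passed also kept their direction. For rHCI against PBS 675 values stayed without passing, and their direction was not compared. Myh8 there went from −4.10 to 0.0760 without PBS replicate 6. With the direction kept, a call was lost for 51 values of PBS against sham and 11 of rHCI against sham, and gained for 12 of rHCI against PBS. Another 25 values of PBS against sham lost their call with a changed direction, all with the composition covariate, and are listed below. The changed genes of PBS against sham numbered 11147 to 11602 when single libraries were left out and 7854 to 12145 under the other settings, apart from 3 with the composition covariate (Saa3, Cthrc1 and Serpinb2). That covariate separates the groups by itself. With it the log2 fold changes of 25 genes reversed without passing: Kcnv2 3.08, Cngb3 0.0345, Nppb −3.70, Myh6 0.99, Glo1 0.47, Hagh 0.32, Gdf15 −1.96, Ttn 3.28, Tnni3 0.91, Scn4b 3.97, Ppara 0.74, Acaa2 1.44, Cox7a1 0.87, mt-Co3 0.47, Ldhb 0.63, Akr1b8 −0.0423, Hmox1 −0.32, Itga11 −1.25, Ctss −0.85, Il1rn −1.79, Erg −0.85, Hgf −0.51, Cdk1 −0.16, Msln −0.73 and Egr2 −0.95. For rHCI against PBS, where edgeR called 0 genes (579 at an unadjusted p under 0.05, 362 to 2066 with single libraries left out and 2019 with limma-voom), DESeq2 called 6, limma-voom 3, single libraries left out 0 to 3 (3 without rHCI replicate 13), and leaving out rHCI 1 and rHCI 13 called 2; the cause was not tested. For rHCI against sham a minimum change of 1.2-fold left 6157 genes, by construction, and single libraries left out gave 9643 to 10606. With an estimated correlation 0 lists were called in each comparison, and by fry 0 for rHCI against PBS; single libraries left out gave 29 to 32, 19 to 25 and 31 to 32 lists. Without rHCI 1 and rHCI 13, 3 lists reversed for rHCI against PBS, pericyte and smooth muscle (newly called, camera adjusted p = 0.0408), cell cycle (call lost, 0.527) and immediate early genes (newly called, 9.52e-05), while 12 other lists lost their call and 5 others gained one, which left 15 called. By fry the oxidative stress list reversed for rHCI against sham (0.0399); the cause was not tested. The move toward sham was −0.167 over genes changed more than 2-fold and −0.129 to −0.0480 with single libraries left out, and the infarct score difference −0.451 to −0.155; the cause was not tested. Recovery of 10% of genes changed 1.2-fold in simulated data is the limit that spread and depth set for rHCI against PBS.

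Other splits of the libraries were compared with the real ones, 100 per comparison. For PBS against sham chance can be excluded for the 11574 genes (1 split as high, the real one; highest other 0) but not for a number of camera calls as high as 31 lists (20; highest other 35). For rHCI against sham it can be excluded for the 10268 genes (1; highest other 2) but not for a number as high as 32 lists (17; highest other 35). These numbers say nothing of single lists, whose scores were therefore compared as well. Of 49 lists, 35 were higher and 7 lower in PBS than in sham hearts, and 33 and 7 in rHCI than in sham hearts, at an adjusted p under 0.05 (exact permutation, smallest possible p 0.00794). Scores are means, and some lists counted as higher had a median log2 fold change below 0. In PBS hearts these were glycolysis (−0.23), oxidative stress (−0.12), methylglyoxal (−0.02) and pericyte genes (−0.00127), and in rHCI hearts glycolysis (−0.20), oxidative stress (−0.04), methylglyoxal (−0.00454) and skeletal muscle (−0.24). For rHCI against PBS chance cannot be excluded for the 21 lists (58; highest other 31), and the 0 genes allow no such test, since every split has as many (100; highest other 3326). The split with 3326 genes set PBS 2, PBS 9, PBS 12, rHCI 3 and rHCI 7 against the rest. These are the 5 infarcted libraries with the highest infarct scores (3.24 to 3.80, the others 2.49 to 3.19), so the split follows the infarct score, a structure of the samples. Whether that score reflects the size of the response or the composition of the tissue taken was not tested.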

Other observations

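The tests of clock genes were chosen only after the result was seen. Genes of the heart's outer lining were higher after infarct and injection. All 14 genes of the epicardium and mesothelium list were higher in PBS than in sham hearts (14 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation), with a median log2 fold change of 2.46. Msln, mesothelin, had 28.0 ± 9.55 CPM in PBS and 3.91 ± 1.32 in sham hearts (SD, n = 5). Lymphatic endothelium genes were higher for 6 and lower for 1 of 9 (6 and 1 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). Phagocyte oxidase and scavenging genes were higher for 14 and lower for 1 of 15, with the same counts adjusted over the list alone (adjusted p = 0.313 with an estimated correlation). Genes of branched-chain amino acid and ketone oxidation were lower for 19 of 20 (19 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). Pericyte and smooth muscle genes went both ways, with 5 higher and 4 lower of 16 (the same adjusted over the list alone; camera adjusted p = 0.895), and so did hypoxia response genes, with 8 higher and 6 lower of 17 (the same adjusted over the list alone; camera adjusted p = 0.961).

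The atrial list had 7 higher and 1 lower of 9 in PBS hearts (the same adjusted over the list alone; adjusted p = 0.491 with an estimated correlation), with Myl7 at 34.5 ± 13.9 against 8.91 ± 5.59 CPM and Myl4 at 46.8 ± 18.9 against 11.1 ± 5.22 CPM (SD, n = 5). Camera called it at adjusted p = 0.0445, and did not without PBS replicate 2 (0.0508), 6 (0.0523) or 12 (0.0522), or with all 15 libraries in 1 fit (0.0595). The skeletal muscle list had 4 higher and 1 lower of 8 (the same adjusted over the list alone; camera adjusted p = 0.871), and its member Tnnt3 had a log2 fold change of 2.554 ± 0.58, or 1.501 without PBS replicate 6. Immediate early and heat shock genes had 10 higher and 4 lower of 20 (the same adjusted over the list alone; camera adjusted p = 0.164), and the transcription factor gene Egr2 had 5.84 ± 1.86 CPM in PBS and 0.739 ± 0.245 in sham hearts.

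Near the end of the X and Y chromosomes, Erdr1, G530011O06Rik and Gm15726 were lower with rHCI than with PBS without passing in edgeR, at log2 fold changes of −1.59 ± 0.30, −2.12 ± 0.30 and −2.77 ± 0.64. Without rHCI replicate 13 they passed, at −2.07, −2.45 and −4.51. G530011O06Rik was higher in PBS than in sham hearts (2.95 ± 0.42, adjusted p = 3.13e-05 by edgeR), and so was Gm15726 (2.69 ± 0.37, adjusted p = 2.46e-05 by edgeR). Erdr1 did not pass there (0.23 ± 0.28, adjusted p = 0.471 by edgeR). Mean CPM in sham, PBS and rHCI hearts was 0.336, 2.62 and 0.603 for G530011O06Rik and 0.117, 0.743 and 0.109 for Gm15726. Sham 18 was the lowest sham library for all 3 genes. G530011O06Rik lies on chromosome X at 169975043 to 169978917 and Gm15726, an antisense gene, at 169979047 to 169985232 (GRCm38). The latter pair was named after values were seen, and reads shared between copies or strands leave the levels of all 3 genes uncertain.

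Clock genes of opposite arms differed between sham and PBS hearts. Of 17 circadian clock genes 5 were higher and 7 lower in PBS hearts (the same adjusted over the list alone; camera adjusted p = 0.733). Dbp had 82.4 ± 29.5 CPM in PBS and 24.5 ± 8.77 in sham hearts (SD, n = 5), Per3 a log2 fold change of 1.31 ± 0.14, and Arntl, of the opposite arm, −0.96 ± 0.18. A clock score, the mean of Dbp, Tef, Hlf, the Per and Nr1d genes, Ciart and Bhlhe41 minus that of Arntl, Npas2, Clock and Nfil3, was higher by 1.37 in PBS than in sham hearts (exact permutation p = 0.00794), with the first arm at 0.514 and the second at −0.860. In rHCI hearts it was higher than in sham hearts by 1.01 (exact permutation p = 0.0397), but rHCI 1, 3 and 7 (0.481, 0.571 and 0.792) lay within the sham range of −0.427 to 0.813, and Arntl did not pass (−0.58 ± 0.31, adjusted p = 0.118 by edgeR). A different time of day at collection may account for this and stays open, since the labels give no time. A graded response would make the score rise with the infarct score. Over the 10 infarcted libraries it leaned the other way, with Pearson's r at −0.641 (permutation p = 0.0450) and Spearman's rho at −0.479 (permutation p = 0.166). These values argue against a graded rise only weakly, since Spearman's rho did not pass. Without rHCI 13 and PBS 12 r was −0.527 (permutation p = 0.180, n = 8). A response to the infarct that is not graded was not tested and stays open.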
